A study of Arabidopsis thaliana with 3 samples.

How the data were processed

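DNA methylation was measured by whole-genome bisulfite sequencing in 3 kinds of sorted material from developing pollen of Arabidopsis thaliana Col-0, with 1 library each from vegetative nuclei, sperm cells and microspores. Per the labels, about 300000 vegetative nuclei, 600000 sperm cells and 1000000 microspores were collected by fluorescence-activated sorting. Their DNA was sheared, given methylated adaptors, converted with bisulfite, and read as paired 50 nt reads from fragments of 340 to 360 bp. Per the submitters' processing notes, CASAVA 1.6.0, Bismark and Bowtie were used with the TAIR10 genome. The versions of Bismark and Bowtie, and any removal of duplicate reads, are not given in the sources used here.

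Each deposited file lists cytosines by position, strand and context, and gives counts of methylated and unmethylated calls and the methylated fraction at each cytosine. The deposited fraction equalled methylated calls over all calls within 1e-06 at every cytosine of the 3 files, so the counts of calls were used throughout. Every listed cytosine had at least 1 call. The files listed 36418773 cytosines for vegetative nuclei, 36989162 for sperm cells and 39072146 for microspores, and no position differed in context or strand between them. Nuclear calls numbered 149890435, 183014300 and 242981424 in that order.

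Gene names and neighbour relations came from a table of the TAIR10.1 assembly. To check that this table could be laid on the files' positions, 3 conserved cytosine or guanine bases of the T-loop were looked for in tRNA genes. They were found at 553 of 622 tRNA genes (88.9%) with no shift, and at no more than 1 of 622 with a shift of 1 bp either way. All printed positions are those of 200 bp windows, or of regions merged from them, on the files' own TAIR10 coordinates. The table gives no strand, so a flank meant 1 kb on either side of a gene where upstream sequence had been planned. Transposable element superfamilies are not in it either, apart from pseudogenes named as Sadhu retrotransposons. Annotated pseudogenes, which in this table include many transposon remnants, were therefore used as a region class.

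Methylation levels are the percent of calls that were methylated, pooled over sites with at least 4 calls in that library. Region classes were protein-coding gene bodies, sequence within 1 kb of them, annotated pseudogenes, Sadhu retrotransposons, other intergenic sequence, and 100 kb windows. A 100 kb window counted as pericentromeric when a running mean over 5 windows held under 30% protein-coding gene sequence, and as arm otherwise. Wilson 95% intervals were computed for pooled levels and single regions. For genome-wide levels, 1000 bootstrap draws of 100 kb blocks gave 95% intervals of the spread along the genome. Wilson intervals, and limits given for a count of 0 (3 counts of the total), cover counting error only, since reads carried no molecular identifiers, and p values likewise take calls as independent.

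Windows of 200 bp were compared between libraries in the CG, CHG and CHH contexts, 9 families of tests in all. A window entered when at least 4 of its sites had at least 4 calls in both libraries and each library had at least 20 calls. Pooled calls were compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment within each context and comparison. A window was called at an adjusted p under 0.01 with a difference of at least 40 points for CG, 30 points for CHG or 20 points for CHH. With 1 library per group, each test compares 2 libraries and not the cell types, and no difference has a replicate check. As a background measured in the same libraries, the calls of one strand were compared with those of the other strand, within and between libraries. This was done at sites with at most 50 calls in every library, so deeper sites have no such background. It held only windows with enough sites and calls on each strand of all 3 libraries. These were 45615 CG, 51983 CHG and 200182 CHH windows, and what is said of the background below holds for them alone. CHH sites of opposite strands are different cytosines, so the CHH background can also hold true differences between strands. Annotation shares are given beside those of windows that could have passed, meaning tested windows where the library that had to be higher was at or above the smallest difference.

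Called windows of the same sign within 200 bp were merged, so levels of a merged region include any uncalled window between called ones. The rule for named genes took, among genes whose body or 1 kb flank overlapped a region with at least 2 called windows, those with the largest pooled difference. It took 10 genes in each direction for CG and for CHH between vegetative nuclei and sperm cells, and 5 in each direction for CHG and for the other comparisons. Every measured imprinted gene and epiallele was added for CG. The rule also provided for transposon families, which the table does not name. Genes of 6 fixed lists were scanned within the gene and 2 kb on either side, beside 10000 random lists drawn from the 500 genes nearest in number of tested windows. Random lists were not matched on methylation level, so a list of methylated genes can hold more windows able to be called lower. Counts for lists are given over all windows tested and adjusted over the list alone. The lists, the thresholds, the comparisons, the rule for named genes and a first set of alternatives were fixed before the data were examined.

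The window test was tested on simulated data with the coverage of each comparison, with 67 windows changed per size. All changed windows were set to a low level in the second library of the comparison and raised in the first. Falls from high levels, as called in CG, were not simulated, so their recovery is not known. For CG between vegetative nuclei and sperm cells, 26.9% of windows changed by 40 points, 64.2% of those changed by 50 points and 86.6% of those changed by 60 points were recovered, with 0 false calls over 206874 windows. Recovery for CHH in the same comparison was 23.9%, 53.7% and 70.1% at 20, 30 and 40 points, with 0 false calls over 410045 windows. Windows changed by exactly the smallest accepted difference were thus mostly missed, in part because sampling alone puts many of them below that difference. Simulated calls were independent, so the 0 false calls do not cover the dependence of calls on one fragment.

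The first set of alternatives was minimums of 1 and 8 calls per site, the mean of per-site levels, subtraction of the chloroplast level, 500 bp windows, a difference minimum raised by 10 points, calls thinned to equal numbers, and a shorter reach for gene lists. Leaving out sites with over 50 calls in any library, using sites with at least 4 calls in all 3 libraries, leaving out a stretch of chromosome 2 (3240001 to 3510000) deeply covered in microspores, and weighting windows alike were chosen after seeing the data. For the last, levels were averaged over 200 bp windows covered in all 3 libraries, without sites over 50 calls in any of them. Chloroplast calls, taken as unmethylated, gave the rate of non-conversion. Mitochondrial calls were left out of all nuclear comparisons. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9 were used.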

Results

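DNA methylation was measured at single cytosines in 3 libraries from developing Arabidopsis pollen. Microspores are the haploid products of meiosis, which divide to give a large vegetative cell and a small generative cell, and the generative cell divides again into the sperm cells. The vegetative nucleus is the companion of the sperm cells and passes no DNA to the embryo. Each material was sequenced in 1 library, so no value below has a replicate. Mean coverage of listed nuclear cytosines was 4.12 calls in vegetative nuclei, 4.96 in sperm cells and 6.24 in microspores. Of microspore calls, 15.8% lay on the chloroplast and 10.7% on the mitochondrial chromosome. In vegetative nuclei the chloroplast share was 0.0275% and in sperm cells 0.0164%. Chloroplast cytosines, which are taken as unmethylated, were called methylated at 0.701%, 0.744% and 0.494% in vegetative nuclei, sperm cells and microspores.

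The comparison of vegetative nuclei with sperm cells asks how DNA methylation differs between the companion nucleus and the gametes of the pollen grain. CHG and CHH methylation of pericentromeric DNA and annotated pseudogenes was higher in vegetative nuclei. In pericentromeric windows the CHH level was 20.8% in vegetative nuclei and 2.91% in sperm cells, a difference of 17.9 points (17.8 to 17.9). Intervals of region classes in this paragraph cover counting error only. With windows weighted alike, the bootstrap over 100 kb blocks gave 14.3 points (13.4 to 15.1) for this difference. Annotated pseudogenes, among them many transposon remnants, had CHH levels of 19.6% and 3.03%, a difference of 16.6 points (16.6 to 16.6). Their CHG level was 70.5% against 56.5%, and that of pericentromeric windows was 57.2% against 45.7%. CG methylation went the other way by a small amount, with 70.6% in vegetative nuclei and 72.9% in sperm cells over pericentromeric windows. Chromosome arms carried little CHH methylation in either, at 2.13% and 1.24%. Sadhu retrotransposons had CHH levels of 4.28% and 1.96%, with a difference of 2.32 points (1.94 to 2.72). Their CHG level was lower in vegetative nuclei, 27.8% against 29.6%, a difference of -1.81 points (-3.42 to -0.175) that turned to 4.16 points with windows weighted alike. Their CG levels were 43.0% and 51.4%, a difference of -8.35 points (-9.86 to -6.83), or -1.57 points with windows weighted alike. Sequence within 1 kb of genes had CG levels of 20.5% in vegetative nuclei and 24.9% in sperm cells. In gene bodies CG levels were 18.9% and 19.7%. The CHH difference of gene bodies, 1.12 points, came to 0.340 points from pooled calls without the deep stretch of chromosome 2 and sites over 50 calls. With 200 bp windows weighted alike, also without sites over 50 calls, it was 0.259 points.

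Over the whole nuclear genome, CHH methylation stood at 7.92% (6.35 to 9.73, bootstrap over 1193 blocks) in vegetative nuclei and 1.67% (1.58 to 1.78) in sperm cells. The difference was 6.25 points (4.78 to 7.98). CHG methylation was 17.6% (16.0 to 19.3) against 13.6% (12.5 to 14.8), a difference of 3.995 points (3.51 to 4.52). CG methylation was 33.3% (31.2 to 36.0) against 34.0% (32.2 to 36.2), and differed by -0.713 points (-1.29 to -0.0432). That small CG difference depended on the choice of sites and on the weighting. It was 1.42 points at sites with at least 8 calls. When windows counted alike it was -1.83 points (-1.92 to -1.75), beside -1.25 points from pooled calls over the same sites. With windows weighted alike the CHH difference was 3.07 points (2.70 to 3.45) and the CHG difference 2.45 points (2.16 to 2.74).

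**Figure D1:**
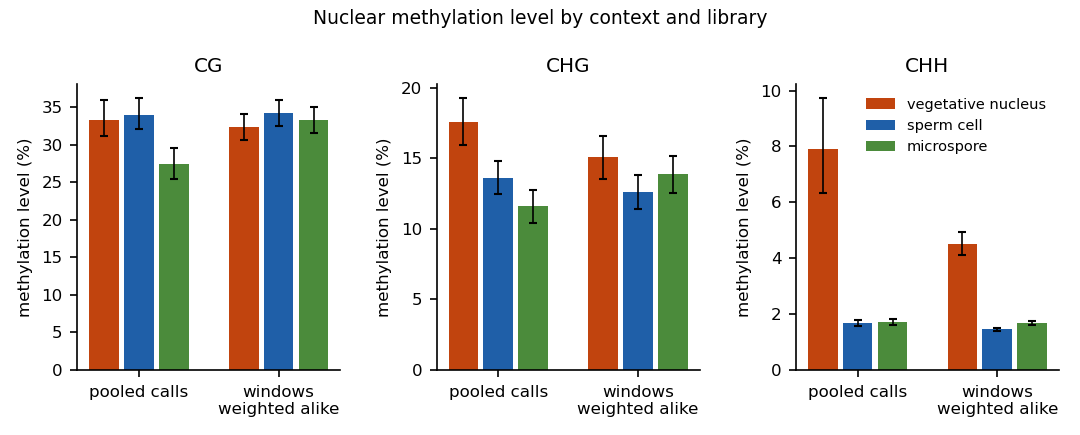
Nuclear methylation level in percent (vertical axes) of the 3 libraries in CG, CHG and CHH, from pooled calls and with 200 bp windows weighted alike, with bars for levels and lines for 95% bootstrap intervals over 100 kb blocks. CHH stands at 7.92% in vegetative nuclei against 1.67% and 1.70% in sperm cells and microspores, and the pooled CG level of microspores (27.5%) moves to 33.3% when windows count alike.

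The CHH excess of vegetative nuclei was largest at sites of the kind CWW, where W is A or T. Such sites were methylated at 10.6% in vegetative nuclei and 2.04% in sperm cells. CWC sites stood at 5.42% and 1.30%, CCW sites at 3.21% and 1.05%, and CCC sites at 2.05% and 0.911%. In CHG, CWG sites had 18.2% against 14.4%, and CCG sites 15.5% against 10.6%. CCC differed by 1.14 points (1.12 to 1.15) and CWW by 8.53 points (8.52 to 8.54), with intervals of counting error only.

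**Figure D2:**
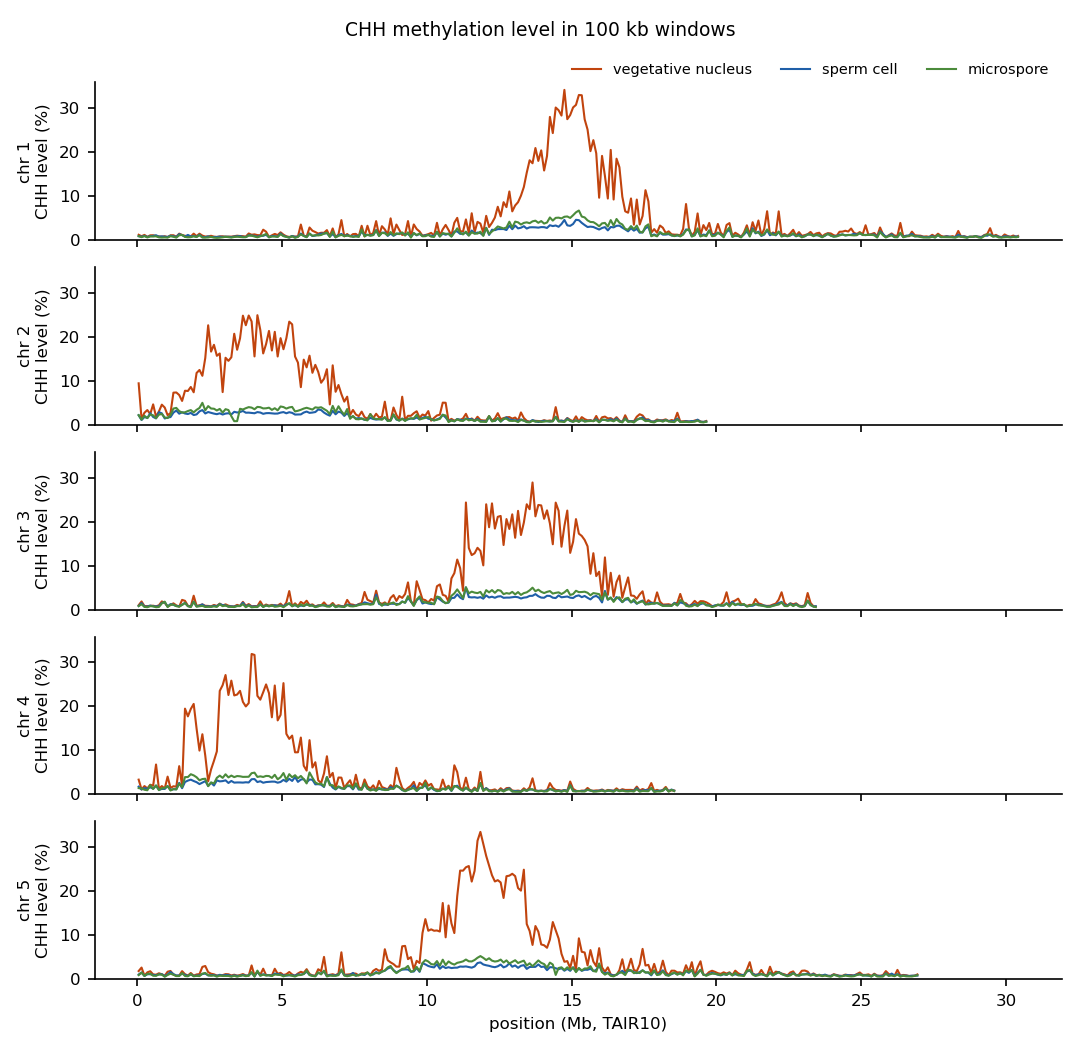
Pooled CHH level in percent (vertical axes), from sites with at most 50 calls, per 100 kb window along the 5 chromosomes (horizontal axes, position in Mb), with 1 line per library. The peaks of the vegetative nucleus line lie in pericentromeric windows, whose level over all sites was 20.8% in vegetative nuclei, 2.91% in sperm cells and 3.25% in microspores.

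At the single loci with the largest differences, short stretches almost fully methylated in CG in sperm cells and microspores had little CG methylation in vegetative nuclei. Such a stretch lay between AT2G15560 and ATHM3, a thioredoxin gene, at chromosome 2, 6790601 to 6791000. Its CG level was 4.44% (1.23 to 14.8) in vegetative nuclei, 98.2% (90.4 to 99.7) in sperm cells and 91.5% in microspores. A region of 4 called windows lay in AT2G06535, a long non-coding RNA gene, at chromosome 2, 6971401 to 6972200, next to AT2G16015, AT2G16016, AT2G16018 and AT2G16019. There the levels were 5.22% (2.55 to 10.4), 96.5% (92.0 to 98.5) and 93.5%. The non-coding RNA gene AT5G38005 had 3.03%, 95.9% and 96.4% at chromosome 5, 15154801 to 15155200. Stretches beside the pseudogenes AT1G43997 and AT4G08134 had 5.77% and 9.76% in vegetative nuclei, against 97.1% and 98.9% in sperm cells.

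Of 206874 CG windows tested by Fisher's exact test, 1880 were lower in vegetative nuclei than in sperm cells and 0 were higher. At an unadjusted p under 0.05, 9810 windows were lower and 1085 higher, and 1 of the higher ones also passed 40 points. With sites of at least 8 calls, 99 were lower (0.257% of windows tested, against 0.909%), and with sites of at least 1 call 5831 were lower and 2 higher. The 1880 windows merged into 1734 regions, of which 132 held at least 2 called windows, and 1071 protein-coding genes lay in or within 1 kb of them. Sequence within 1 kb of genes held 32.3% of called windows but 5.16% of windows that could have passed, and other intergenic sequence held 43.8% against 19.6%. Gene bodies held 14.2% against 45.8%, and pseudogenes 9.68% against 29.5%. In the called windows CHG methylation was lower too, at 27.0% in vegetative nuclei and 46.9% in sperm cells, with 106 of 714 tested windows called lower and 0 higher. CHH methylation in the same windows was 8.42% against 5.43%. The median CG level of called windows was 29.5% in vegetative nuclei, 95.2% in sperm cells and 92.9% in microspores. Opposite strands of the same library, compared the same way, gave calls in 0.160% of windows for vegetative nuclei and 0.147% for sperm cells, against 0.421% and 0.463% for the 2 pairings of strands from different libraries. Those pairings gave 162 and 180 windows lower in vegetative nuclei and 30 and 31 higher, beside 25 to 42 per direction within either library.

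**Figure D3:**
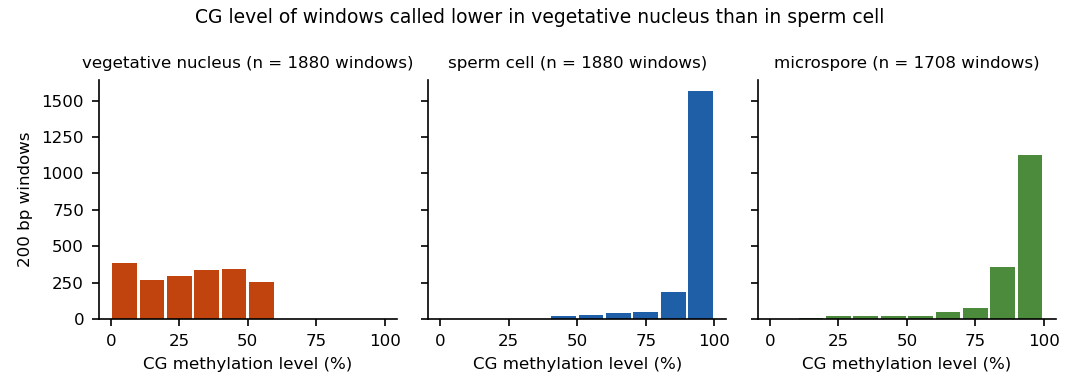
Number of 200 bp windows (vertical axes) by CG methylation level in percent (horizontal axes) for the 1880 windows lower in vegetative nuclei than in sperm cells, with 1 panel per library and 1708 windows with enough calls in microspores. The levels of vegetative nuclei spread widely around a median of 29.5%, and those of sperm cells and microspores crowd near medians of 95.2% and 92.9%.

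Epialleles, genes whose activity is known to follow heritable methylation states, were among these loci. QQS, an orphan gene that affects starch content, had no methylated CG call in vegetative nuclei at chromosome 3, 12349001 to 12349200. There 0 of 46 calls were methylated, which allows up to 6.52%, against 97.3% in sperm cells and 93.1% in microspores (adjusted p = 2.67e-19, Fisher's exact test). The calls compared between vegetative nuclei and sperm cells all lay on the minus strand, at 4 to 11 per site, so the other strand offers no check. SDC, an F-box gene silenced through methylated tandem repeats, had 13.3%, 90% and 88.6% (adjusted p = 1.67e-09, Fisher's exact test). ROS1, a DNA glycosylase that removes methylcytosine, had 0 of 26 calls methylated in vegetative nuclei, which allows up to 11.5%, against 89.3% in sperm cells and 72.5% in microspores at chromosome 2, 15314801 to 15315000. In total 3 of 7 epialleles had a window called lower, and 53 of 10000 random lists matched on tested windows, but not on methylation level, had as many. FWA, IBM1, PAI2 and BNS had no call. The window of FWA with the largest change had 39.7% in vegetative nuclei and 55.3% in sperm cells, and that of IBM1, a histone demethylase gene, had 70.4% and 100%. PAI2 had 0 of 27 and 0 of 20 methylated calls, which allow up to 11.1% and 15%, and BNS had 97.9% and 89.6%.

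**Figure D4:**
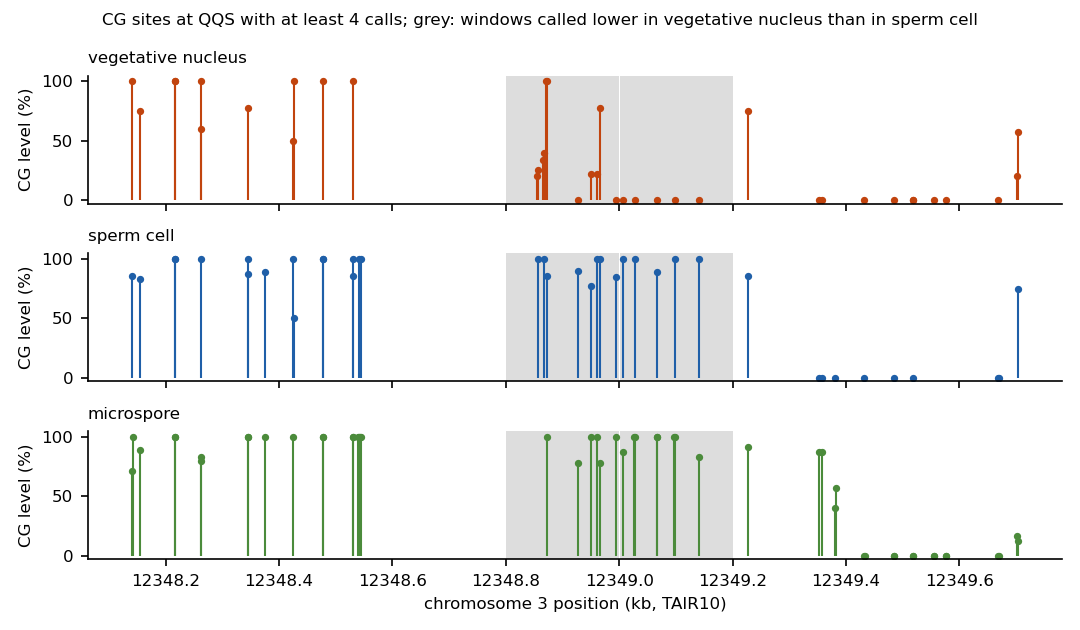
CG methylation level in percent (vertical axes) of single sites with at least 4 calls along chromosome 3 at QQS (horizontal axis, position in kb), with 1 panel per library and the called windows in grey. Within 12349001 to 12349200 the pooled level was 97.3% in sperm cells and 93.1% in microspores, and 0 of 46 calls were methylated in vegetative nuclei.

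Among maternally expressed imprinted genes, 2 of 9 had a CG window called lower in vegetative nuclei than in sperm cells, and 951 of 10000 random lists had as many. These were SDC and HDG9, a homeodomain gene, with 37.5%, 93.1% and 86.7% in vegetative nuclei, sperm cells and microspores. The MADS-box gene AGL36 had 67.2% against 90.7%, a gap of less than 40 points. The Polycomb genes MEA and FIS2 had 1.08% and 11.1% in vegetative nuclei at their most changed windows, and 0 of 169 and 0 of 49 methylated calls in sperm cells, which allow up to 1.78% and 6.12%. MPC had 92.6% and 87.3%, HDG8 had 3.70% and 9.80%, and DOGL4 had 0 of 128 calls (up to 2.34%) and 1.504%. Of the 9 paternally expressed imprinted genes 0 had a call. Their most changed windows included YUC10, an auxin synthesis gene, at 72.2% and 92.5%, ADM at 74.5% and 96.6%, PHE1 at 60.4% and 78%, SUVH8 at 5.45% and 13.9%, and AGL92 at 91.9% and 93.4%. HDG3, SUVH7, VIM5 and PKR2 had at most 3.57% in either library at theirs.

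Genes of the DNA methylation machinery had CG calls at 2 of 18 members, and 2139 of 10000 random lists had as many. They were ROS1 and its relative DML3, which had 5.48% in vegetative nuclei, 77.3% in sperm cells and 44.2% in microspores at chromosome 4, 16320801 to 16321000. Of vegetative cell and pollen tube genes, 1 of 10 had a call, AGL65, a MADS-box gene of pollen, with 13.0%, 72.4% and 60.4%. Sperm cell genes had calls at 0 of 7 members. Scanning 1 kb in place of 2 kb on either side left 1 gene of the methylation machinery and 0 vegetative genes. Adjusted over the list alone, the CG counts of all 6 lists were the same as over all windows tested.

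CHH methylation rose at far more windows than it fell between sperm cells and vegetative nuclei. KCO2 and KCO3, neighbouring potassium channel genes, had 96.6% (91.5 to 98.7) in vegetative nuclei, 31.0% (23.7 to 39.4) in sperm cells and 59.7% in microspores at chromosome 5, 18808801 to 18809200. Beside BGLU34, a beta-glucosidase gene, the levels were 81.0%, 16.3% and 19.8%, and beside AT2G22590 they were 93.2%, 26.7% and 53.3%. Stretches next to the pseudogenes AT2G12815 and AT2G12820 had 73.2% against 6.90%, those next to the non-coding RNA genes AT5G04765 and AT5G04775 had 70.7% against 5.36%, and the stretch at AT4G07965 and AT4G07967 had 62.7% against 1.27%. Among windows called lower, whose number did not exceed the strand background, was ICK1, an inhibitor of cyclin-dependent kinases, with 2.27% (0.625 to 7.91) in vegetative nuclei, 48.5% (39.0 to 58.1) in sperm cells and 34.4% in microspores. AT2G32070 and PUR ALPHA-1 shared a region with 8.13% against 49.5%, AT5G06425 and AT5G42940 a region with 2.94% against 38.5%, and AT2G04015 had 2.04% against 35.8%. PHT4;5, a phosphate transporter gene, and AT5G20390 had 4.63% against 31.3%, and AT5G18735 and AT5G18740 had 5.88% against 30.5%, but neither region passed at sites with at least 8 calls.

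Of 410045 CHH windows, 24739 rose and 165 fell by Fisher's exact test. The higher windows merged into 6830 regions of up to 19200 bp and lay in or within 1 kb of 2874 of 4843 annotated pseudogenes and 1200 of 27444 protein-coding genes. Pericentromeric sequence held 88.1% of them, beside 80.4% of windows that could have passed, while 95.8% of the lower windows lay in the arms, beside 86.6%. Opposite strands of vegetative nuclei gave calls in 0.844% of windows, against 8.25% and 8.35% for strands from the different libraries. By direction, strands of different libraries gave 89 and 87 windows lower in vegetative nuclei of 200182 tested. Strands of the same library gave 858 and 832 per direction in vegetative nuclei and 90 and 90 in sperm cells, so the CHH falls were not above this background. CHH sites differ between opposite strands, so it may also count true strand differences and cannot show that the falls are noise. Epialleles had a higher CHH window at 3 of 7 members (SDC, QQS and ROS1), with as many in 95 of 10000 random lists. Maternally expressed imprinted genes had such a window at 3 of 9 (SDC, DOGL4 and HDG9), with as many in 241, though only 1 within 1 kb. SDC had 82.1% in vegetative nuclei, 22.7% in sperm cells and 23.3% in microspores, and DOGL4 had 51.4%, 8.24% and 30.6%. Further lists had calls at 2 of 18 methylation genes (ROS1 and DRM2, the de novo methyltransferase), 1 of 7 sperm cell genes, 1 of 10 vegetative cell genes and 0 of 9 paternally expressed genes. Adjusted over the list alone, these CHH counts were the same. The QQS window, at 23.0% and 2.23%, fell short of 20 points when sites needed 1 or 8 calls.

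CHG windows moved both ways between vegetative nuclei and sperm cells. Near COL3, a CONSTANS-like gene, AT2G24780 and the ADP-ribosylation factor gene ARF3, the CHG level was 70.5% (59.6 to 79.5) in vegetative nuclei and 17.6% (11.1 to 26.7) in sperm cells. The pseudogenes AT2G06110 and AT2G13240 had 91.8% against 49.0% and 74.1% against 38.3%, the first without a call at sites with at least 8 calls and the second without one at a minimum of 1. In the other direction, AT3G44703 had 3.77% in vegetative nuclei and 90.6% in sperm cells, AT4G11373 with its neighbours AT4G11375 and AT4G11380 had 4% and 80%, and AT1G19086 had 17.02% and 89.7%. Fisher's exact test called 1109 windows higher and 379 lower of 239612 tested. With a minimum difference raised by 10 points the lower windows outnumbered the higher, 334 to 237. Of 51983 windows testable on each strand, strands of different libraries gave 780 and 701 higher and 22 and 15 lower in vegetative nuclei. Strands of the same library gave 0 within vegetative nuclei and 10 and 11 within sperm cells. Lower CHG windows of that set thus lay little above the background, which covers only part of the 239612 windows tested. Pseudogenes held 71.1% of the higher windows, beside 59.4% of those that could have passed. Sequence within 1 kb of genes held 22.2% of the lower windows, beside 5.59%.

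Around the ends of pseudogenes of at least 1 kb, at sites with at most 50 calls, the CHH level of vegetative nuclei was 21.3% just outside and 18.0% just inside, with 3.28% and 2.99% in sperm cells and 4.82% and 4.21% in microspores. Protein-coding genes of at least 1 kb had low CG methylation near their ends and rising levels inside. Each gene was followed only to its middle, so bins far inside hold long genes alone, and the rise mixes position with gene length. In the bin starting 1900 bp inside, CG levels were 44.6% in vegetative nuclei, 46.5% in sperm cells and 43.1% in microspores, against 5.83%, 7.45% and 5.50% just outside the ends. In flanks starting 1000 bp outside genes, CHH levels were 2.13%, 1.37% and 1.35%.

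**Figure D5:**
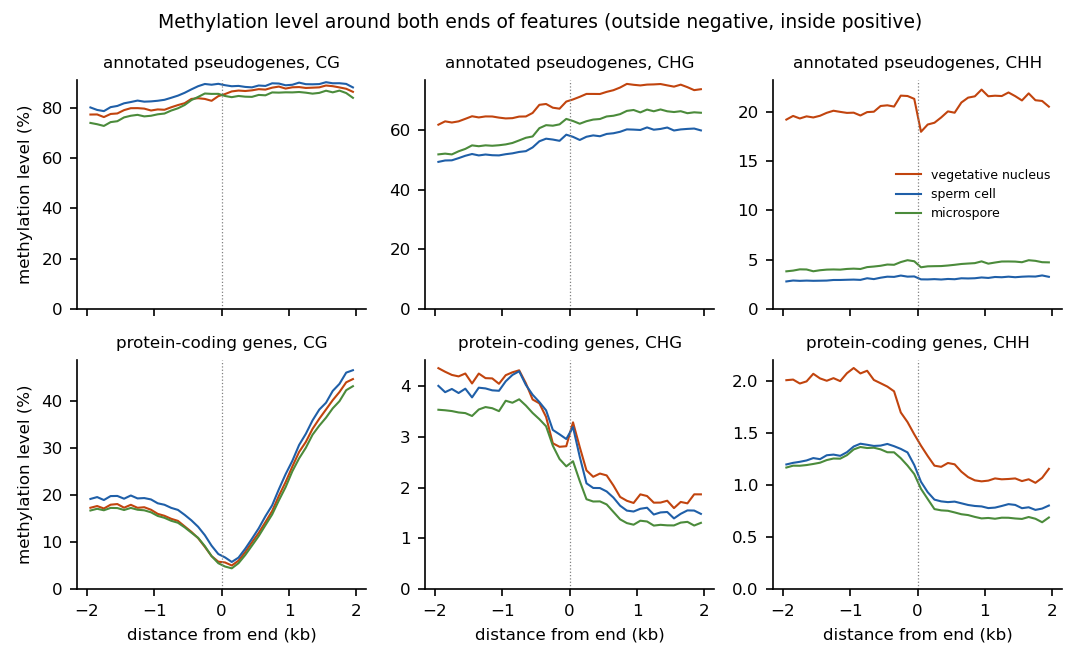
Pooled methylation level in percent (vertical axes) in 100 bp bins around both ends of annotated pseudogenes (upper panels) and protein-coding genes (lower panels) in CG, CHG and CHH, by distance from the end in kb (horizontal axes, outside negative), at sites with at most 50 calls, with 1 line per library. The CHH line of vegetative nuclei lies above the others, at 21.3% against 3.28% and 4.82% just outside pseudogenes, and CG dips at gene ends, to 5.83% in vegetative nuclei just outside.

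The comparison of vegetative nuclei with microspores asks what differs between this nucleus and the cell it descends from. Many stretches methylated in CG in microspores had less CG methylation in vegetative nuclei. Over the 2296 CG windows called lower, median levels were 27.6% in vegetative nuclei and 93.5% in microspores, and the genes named here had the largest differences. AT2G21100 and AT2G21105, with AT2G21090 beside them, had 3.19% (1.09 to 8.97) in vegetative nuclei, 100% (94.1 to 100) in microspores and 94.4% in sperm cells at chromosome 2, 9048201 to 9048600. AT1G06148 had 0 of 65 calls methylated in vegetative nuclei, which allows up to 4.62%, against 95.7% in microspores. AT2G15560 was again among the most changed, with 0 of 46 calls (up to 6.52%) against 93.9%. CHH methylation was higher in vegetative nuclei around HDG9 and UGP2, a UDP-glucose pyrophosphorylase gene, with 89.6% (82.4 to 94.1) against 17.3% (10.6 to 26.9). At the pseudogenes AT5G34900 and AT4G04635 and at AT3G45530 it was 82.4%, 88.0% and 92.9% in vegetative nuclei and 5.96%, 17.04% and 21.8% in microspores. IAA8, an auxin response repressor, had 10.2% (7.42 to 14.0) against 59.2% (53.7 to 64.5) over 5 called windows, AT2G04015 had 5.06% against 48.2%, AT1G05430 had 27.2% against 72.2%, and AT1G06327 and AT1G06333 shared a region with 20.3% against 71.9%. The regions of AT4G04635, AT1G05430, AT1G06327 and AT1G06333 lost their calls at sites with at least 8 calls, and the last pair also at a minimum of 1.

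Fisher's exact test called 2296 of 229846 CG windows lower and 355 higher in vegetative nuclei than in microspores. The lower ones again lay within 1 kb of genes more than windows that could have passed, 31.2% beside 5.14%. Of the higher ones 187 lay in a 270000 bp stretch of chromosome 2, 3240001 to 3510000, where microspores had 223 calls per CG site and vegetative nuclei 8.34. The genes named in CG there were AT2G07617, AT2G07621 and AT2G07684, with 99.0% in vegetative nuclei and 3.71% in microspores, and AT2G07715 and AT2G00480, with 96.3% and 1.22%. In CHG they were AT2G07636, AT2G07637, AT2G07692, AT2G07693 and AT2G05245, with 88.0% and 1.90%. The stretch holds a nuclear copy of mitochondrial DNA. On the mitochondrial chromosome itself, microspores had 485 calls per CG site and a CG level of 1.18%. Low microspore levels in the stretch may thus be those of mitochondrial reads and cannot be read as nuclear methylation. Without sites over 50 calls the higher windows numbered 169 for CG and 125 for CHG. At sites with at least 8 calls the balance turned, with 124 higher and 107 lower in CG and 118 higher and 24 lower in CHG. CHH windows rose at 22510 and fell at 330 of 431021, and CHG windows rose at 325 and fell at 533 of 265476. CHH calls lower in vegetative nuclei, IAA8 among them, were not above the strand background, with 101 and 112 between libraries, beside 858 and 832 within vegetative nuclei and 101 and 108 within microspores. The lower CHG windows included AT3G44703 at 5.08% against 86.1%, the pseudogene AT3G33148 at 3.23% against 80%, and AT4G11373 with AT4G11375 and AT4G11380 at 7.95% against 77.5%.

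Epialleles fell in CG at 4 of 7 members between microspores and vegetative nuclei, namely QQS, SDC, ROS1 and IBM1. As many were found in 2 of 10000 random lists, which were not matched on methylation level. This count and that against sperm cells share the vegetative nucleus library, so they are not independent. Vegetative cell and pollen tube genes fell at 3 of 10, with as many in 259 random lists, though at only 1 of 10 within 1 kb. ANX2, a receptor kinase of the pollen tube, had 16% in vegetative nuclei and 83.3% in microspores, and AGL104, a MADS-box gene of pollen, had 0 of 34 calls methylated (up to 8.82%) against 93.0% (adjusted p = 5.44e-18, Fisher's exact test). AGL65 was the third. Further CG calls fell on 2 of 9 maternally and 0 of 9 paternally expressed imprinted genes, 1 of 18 methylation genes and 1 of 7 sperm cell genes (GEX1, 28.8% against 68.9%). CHH windows rose at 2 of 9 maternally expressed genes, 2 of 7 epialleles, 2 of 18 methylation genes and 1 of 7 sperm cell genes. They fell at AGO4, an effector of RNA-directed methylation with 1.75% against 39.2% (more than 1 kb from the gene), and at AGL104 with 7.14% against 35.2%, calls of the direction that did not exceed the strand background. Adjusted over the list alone, these counts were the same except that AGL104 lost its CHH call. The calls of IBM1 and GEX1 did not pass when sites needed 1 call, and the calls of ANX2, AGL65, HDG9 and ROS1 in CG did not when sites needed 8.

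Pooled levels of microspores lay below those of vegetative nuclei in all 3 contexts, by 5.87 points in CG (4.23 to 7.80), 5.98 points in CHG (5.17 to 6.93) and 6.21 points in CHH (4.73 to 7.97). Coverage differed as well. Microspores had 9.08 calls per site in windows with under 20% CG methylation in vegetative nuclei and 7.86 in windows with over 80%, while vegetative nuclei had 6.73 and 6.95. With windows weighted alike, the CG level of vegetative nuclei was the lower, with a difference of -0.935 points (-1.02 to -0.855). The CHG difference became 1.16 points and the CHH difference 2.84 points.

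The comparison of sperm cells with microspores asks what changed between the haploid precursor and the gametes. CHH methylation was low in both, at 1.67% and 1.70% (1.596 to 1.82), a difference of -0.0324 points (-0.0867 to 0.0310). Without sites over 50 calls the difference was -0.0995 points (-0.121 to -0.0788), and with windows weighted alike -0.226 points. CHH was 2.91% against 3.25% in pericentromeric windows (-0.882 points without the deep stretch of chromosome 2) and 3.03% against 4.06% in pseudogenes. Called CG windows were more often higher than lower in sperm cells, but a few named genes had high CG methylation in microspores and low in sperm cells. MRD1, HEI10, a gene of meiotic crossovers, and the non-coding AT1G07887 share such a region at chromosome 1, 19963601 to 19964200. It had 5.59% (3.61 to 8.56) in sperm cells, 69.5% (63.9 to 74.5) in microspores and 7.66% in vegetative nuclei in CG, and 8.64%, 63.4% and 8.42% in CHG. AT3G29130 had 1.47% in sperm cells and 69.2% in microspores, and a stretch within 1 kb of AT1G57620 had 12.7% and 76.4%. CHH was lower in sperm cells at MAP2A, a methionine aminopeptidase gene, and AT2G44175, with 31.6% (27.6 to 35.9) against 65.2% (61.4 to 68.8). The same held at emb1129 with 23.3% against 57.4%, AT5G35915 with 22.4% against 56.9% and AT2G03972 with 25.6% against 57.7%. In the other direction, whose calls did not exceed the strand background, CHH was higher at AT2G45290 and AT2G45300 with 61.7% against 19.5%. The same held at AT3G42434 with 49.8% against 13.0%. In and beside AT5G25000, also within 1 kb of AT5G25010, 2 called windows were higher by 31.4 points. AT5G35915 lost its call at a minimum of 1 call per site and AT2G03972 at a minimum of 8.

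By Fisher's exact test 559 of 273507 CG windows were higher and 149 lower in sperm cells. The lower windows made 145 regions, of which 3 held at least 2 called windows, and 194 protein-coding genes lay in or within 1 kb of them. Their median CG level was 2.63% in sperm cells and 60% in microspores, and 4.60% in vegetative nuclei over the 113 windows with enough calls there. Of windows tested against microspores in both comparisons, 101 were lower in sperm cells, and 62 of these were lower in vegetative nuclei too. Likewise 252 of 428 windows higher in sperm cells were higher in vegetative nuclei. Both comparisons share the single microspore library, so a property of that library cannot be told apart from a change between stages. Gene bodies held 79.2% of the lower windows, beside 48.0% of those that could have passed, and arms held 91.3%, beside 56.8%. Of 45615 CG windows testable on each strand, strands of different libraries gave 26 and 25 lower and 101 and 114 higher in sperm cells. Strands of the same library gave 25 and 42 within sperm cells and 11 and 7 within microspores. The lower CG windows of that set were thus not above this background, which covers only part of the 273507 windows tested. In CHG strands of different libraries gave 5 and 7 of 51983 windows higher in sperm cells, beside 10 and 11 within sperm cells. Higher CHG windows at sites with at most 50 calls were thus not above it either. Deeper sites have no such background, so it does not cover most of the 217 higher CHG windows. The deep stretch of chromosome 2 held 200 of the higher CG windows and 201 of the 217 higher CHG windows, and microspore levels there may be those of mitochondrial reads. Genes named there were AT2G07625, AT2G07669 and AT2G07678 with 99.3% in sperm cells and 2.76% in microspores, AT2G07723 and AT2G07815 with 98.3% and 1.78%, and in CHG AT2G07656, AT2G07729, AT2G07626, AT2G07682 and AT2G07655, with 71.6% to 75% and 0.796% to 2.59%. Without sites over 50 calls, 354 CG and 20 CHG windows were higher, and the CHG windows that were lower, at 92, then outnumbered the higher. CHG was lower at 131 of 308619 windows, among them AT2G04855 and AT2G05105 with 44.8% in sperm cells, 79.7% in microspores and 77.6% in vegetative nuclei, a region without a call at sites with at least 8 calls. CHH windows were higher at 90 and lower at 265 of 462057. Strands of different libraries gave CHH calls in 0.115% and 0.124% of windows, close to the 0.0899% and 0.104% of strands from the same library. Single CHH calls of this comparison thus lay little above that background. By direction, 81 and 72 windows were higher and 168 and 159 lower in sperm cells, beside 90 and 90 within sperm cells and 101 and 108 within microspores. Higher CHH windows were therefore not above it.

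DNA methylation genes had CG windows higher in sperm cells at 4 of 18, and 36 of 10000 random lists had as many. Within 1 kb this held for 2 of 18, and 696 of 10000 random lists had as many. DRM2 had 68.4% in sperm cells and 24.5% in microspores, and the glycosylase gene DML2 had 56.5% and 7.14%. The small-RNA enzyme genes DCL3 and RDR6 had 56.3% against 6.25% and 64.4% against 10%. DCL3 had no call when sites needed 1 call, and DRM2 and RDR6 had none when they needed 8. PHE1, a paternally expressed MADS-box gene, had 72.2% against 30.8% (adjusted p = 0.00172, Fisher's exact test), without a call at a minimum of 1 call per site or within 1 kb. Among vegetative cell genes AGL65 was higher and MYB120, a pollen tube regulator, was lower, with 29.2% against 79.6% at a window more than 1 kb away. Epialleles, maternally expressed imprinted genes and sperm cell genes had no CG call in this comparison. In CHH, 1 of 9 maternally expressed genes was higher (HDG9, 28.7% against 4.76%) and 1 of 10 vegetative cell genes was lower (AGL66, 33.7% against 64.7%), and neither passed at a minimum of 1 call per site. HDG9 also had no such call within 1 kb, and higher CHH windows of this comparison were not above the strand background. Adjusted over the list alone, counts were the same except for a CHH call at DOGL4.

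Pooled CG levels were 34.0% in sperm cells and 27.5% (25.4 to 29.6) in microspores, a difference of 6.59 points (5.14 to 8.31), and CHG levels were 13.6% and 11.6% (10.4 to 12.8), a difference of 1.98 points (1.44 to 2.61). In pericentromeric windows CG stood at 72.9% and 56.5%, in arms at 20.7% and 18.0%. The deep stretch of chromosome 2 is pericentromeric, and without it the pericentromeric gap of 16.5 points was 2.64 points, with 72.8% in sperm cells and 70.2% in microspores. These pooled gaps shrank or turned with windows weighted alike, to 0.898 points (0.859 to 0.935) in CG and -1.29 points (-1.43 to -1.15) in CHG. Pseudogenes then had CHG levels of 69.0% in vegetative nuclei, 56.2% in sperm cells and 62.8% in microspores.

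Windows lower in CG or higher in CHH in vegetative nuclei were largely shared between the comparisons with sperm cells and with microspores. Of CG windows tested in both, 1582 were lower against sperm cells and 1628 against microspores, and 1275 were lower against both. CHH windows higher in vegetative nuclei numbered 24270 and 21568, and 18553 were shared. In CHG 239 lower windows were shared of 329 and 427, but only 26 higher ones of 1075 and 283, and in CHH 63 lower windows were shared of 145 and 269. Independent lists would share 13.1 CG, 1320 CHH, 0.611 lower CHG, 1.32 higher CHG and 0.0984 lower CHH windows. The comparisons share the vegetative nucleus library, so they are not independent. Libraries simulated without a difference shared 0 windows, but they also gave 0 calls, so this does not measure what the shared library adds.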

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

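The test of variants on 1 strand was chosen before its result was seen, and the other tests of this part, on the microspore level, depth, overconversion, cell type and CHH, only after. Calls placed on the mitochondrial chromosome, which the comparisons of the report do not use, had methylated CG calls above what a count of 0 would allow. Their CG level was 90.2% in vegetative nuclei and 91.5% in sperm cells, but 1.18% in microspores, near that library's chloroplast CG level of 0.488%. Calls per site were 6.97, 8.04 and 485 in that order. The stretch of chromosome 2 from 3240001 to 3510000, home of a nuclear copy of mitochondrial DNA, had CG levels of 93.6%, 93.9% and 2.15%, with 8.34, 9.31 and 223 calls per site. In vegetative nuclei CHG and CHH levels were 72.9% and 18.5% on the mitochondrial chromosome and 73.6% and 18.8% in the stretch. In sperm cells they were 58.4% and 2.61% against 57.1% and 2.56%. The high levels on the mitochondrial chromosome may thus be those of reads from the nuclear copy. They cannot be read as methylation of mitochondrial DNA.

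The pooled CG level of microspores lay 6.59 points below that of sperm cells. Organelle reads placed on nuclear copies are not the whole of it, because the gap was still 5.18 points without the deep stretch of chromosome 2 and sites over 50 calls, although on chromosome 2 sperm cells and microspores had 39.2% and 25.8% with those sites and 37.4% and 31.3% without sites over 50 calls. Fewer calls at methylated DNA in the microspore library stay open for part of it, since the gap was 0.898 points with windows weighted alike and 3.61 points from pooled calls over the same sites, so that the choice of sites changed it too. Pollen stage cannot be told apart from library preparation, because each stage has 1 library. The lower bound of the interval with windows weighted alike, 0.859 points, lies above 0, and an earlier test on windows above 90% in vegetative nuclei gave a median gap between sperm cells and microspores of 1.43 points.

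CG windows were lower in vegetative nuclei than in sperm cells at 1880 places and higher at 0. Overconversion would lower methylated windows alike, but over all windows above 90% in microspores the median gap was 1.78 points. Variants on 1 strand would spare the other strand, but 89.7% of the 985 called windows with enough calls per strand were lower by at least 20 points on both. The rest of the 1880 could not be checked in this way. Calling windows on a pooled fall may itself favour those lower on both strands. With calls thinned to equal numbers 1676 windows were lower and 0 higher, which argues against unequal call numbers as the source of most of them. Low depth in itself stays open, since 0.257% of tested windows were lower at sites with at least 8 calls against 0.909% before. Those sites left a smaller set of windows, 38567 against 206874. Called windows also had fewer calls per site in each library than others that could have passed. They had 6.18 against 8.26 in vegetative nuclei, 7.44 against 9.66 in sperm cells and 6.995 against 10.08 in microspores. A difference between cell types stays open as a hypothesis with 80.6% of the windows lower against both other libraries, and it cannot be told apart from an unknown fault of the single vegetative nucleus library, which both comparisons share.

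CHH methylation was 6.25 points higher in vegetative nuclei than in sperm cells. Incomplete conversion would raise the chloroplast too, and that CHH level differed by 0.0295 points. Reads protected from conversion would raise all sequence alike, but the CCC difference was 13.3% of the CWW difference, and deeply covered repeats left a gap of 4.57 points when sites over 50 calls were left out. A cell type difference may explain the rest, as a hypothesis, with 76.4% of higher windows higher against microspores too. It cannot be told apart from an unknown property of the single vegetative nucleus library, which both comparisons share.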

How the results depend on the processing

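Leaving out sites over 50 calls, requiring 4 calls in all 3 libraries, leaving out the deep stretch of chromosome 2, weighting windows alike, the chloroplast minimum and the checks of single regions were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Of 72 alternative values of genome-wide differences, 4 reversed, 65 moved past their counting interval and 3 did not. Among region classes 22 of 264 reversed and 194 moved, and among trinucleotides 17 of 18 moved. Of 346 values of single regions 0 reversed, 35 no longer passed, and 71 alternatives gave no value because too few sites were left. The 4 overlaps between comparisons stayed within 1.5 times. The balance of higher against lower windows turned in 5 of 54 alternatives, all in CG or CHG, whose counts are among those below. A planned reach upstream of genes became either side, since the table gives no strand. The cause was not tested for any value below.

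Genome-wide differences are given in points for vegetative nuclei minus sperm cells, vegetative nuclei minus microspores, and sperm cells minus microspores. With at least 1 call per site they were -1.87, 3.66 and 5.53 in CG, 2.96, 4.32 and 1.36 in CHG, and 5.16 and 5.13 for the first pair in CHH. With at least 8 calls they were 1.42 (reversed), 11.9 and 10.5 in CG, 6.39, 11.1 and 4.67 in CHG, and 10.2, 10.4 and 0.159 (reversed) in CHH. The mean of per-site levels gave -1.40, 1.86 and 3.26 in CG, 3.34, 3.575 and 0.233 in CHG, and 4.202, 4.05 and -0.156 in CHH. Subtracting the chloroplast level gave -0.492, 5.78 and 6.27 in CG, 4.04, 5.84 and 1.80 in CHG, and 6.26, 6.04 and -0.217 in CHH. Without sites over 50 calls they were -1.32, 3.90 and 5.22 in CG, 3.65, 5.20 and 1.55 in CHG, and 4.57, 4.47 and -0.0996 in CHH. With 4 calls in all 3 libraries they were -1.15, 3.53 and 4.68 in CG, 3.21, 4.04 and 0.823 in CHG, and 6.68, 6.54 and -0.136 in CHH. Without the deep stretch of chromosome 2, those that moved were 4.48 and 5.20 for the last pair in CG, 5.45 and 1.47 in CHG, and 6.24, 6.15 and -0.0829 in CHH. Windows weighted alike gave -1.83, -0.935 (reversed) and 0.898 in CG, 2.45, 1.16 and -1.29 (reversed) in CHG, and 3.07, 2.84 and -0.226 in CHH.

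CHH differences between vegetative nuclei and sperm cells are given for pericentromeric windows, pseudogenes, arms and gene bodies. They were 16.96, 15.9, 0.799 and 0.855 with at least 1 call, 19.4, 18.1, 1.18 and 2.92 with at least 8 calls, and 16.2, 16.1, 0.790 and 0.329 as means of per-site levels. They were 18.0, 16.7, 0.866 and 1.10 after subtracting the chloroplast level, and 18.0, 16.4, 0.861 and 1.38 with 4 calls in all 3 libraries. With windows weighted alike they were 14.3, 14.8, 0.639 and 0.259, and without sites over 50 calls 16.8, 0.844 and 0.342 outside pseudogenes. Gene bodies gave 1.11 without the deep stretch. The small CHG difference within 1 kb of genes reversed to -0.702 with at least 1 call, -0.373 as a mean of per-site levels and -0.46 without sites over 50 calls. In Sadhu retrotransposons it reversed to 0.0172 as a mean of per-site levels, 0.716 with 4 calls in all 3 libraries and 4.16 with windows alike. Between sperm cells and microspores, CHG in pseudogenes reversed to -0.301 (at least 1 call), -5.45 (per-site mean), -4.45 (no sites over 50 calls), -0.824 (4 calls in all 3), -4.59 (no deep stretch) and -6.57 (windows alike). Pericentromeric CHG reversed to -3.79 (per-site mean), -2.93 (no sites over 50 calls), -4.13 (no deep stretch) and -5.72 (windows alike). With windows alike CHG in arms reversed to -0.328 and in gene bodies to -0.0366. CHH in arms reversed to -0.00672 (per-site mean), -0.151 (chloroplast subtracted) and -0.0389 (windows alike), and in gene bodies to -0.0752 (chloroplast subtracted). At a minimum of 1 call CCG differed by 4.14, CCW by 1.89, CWC by 3.50, CWG by 2.63 and CWW by 6.99 points. The chloroplast CHG level of vegetative nuclei was 0.463% at sites with at least 4 calls.

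For vegetative nuclei against sperm cells, a minimum of 1 call gave 2 higher and 5831 lower in CG, 1252 lower in CHG and 822 lower in CHH, and a minimum of 8 gave 99 lower in CG, 334 higher and 24 lower in CHG, and 10070 higher and 9 lower in CHH. Windows of 500 bp gave 435 higher and 453 lower in CHG and 11687 higher and 93 lower in CHH, and a minimum difference raised by 10 points gave 237 higher and 334 lower in CHG and 8136 higher and 97 lower in CHH. For vegetative nuclei against microspores, a minimum of 1 call gave 6126 lower in CG, 495 higher and 1777 lower in CHG and 1251 lower in CHH, and a minimum of 8 gave 124 higher and 107 lower in CG, 118 and 24 in CHG, and 8155 and 21 in CHH. Windows of 500 bp gave 186 higher in CG and 10479 higher and 190 lower in CHH, and the raised minimum gave 7016 higher and 191 lower in CHH. Without sites over 50 calls 169 were higher in CG and 125 in CHG. For sperm cells against microspores, a minimum of 8 calls gave 210 higher and 32 lower in CG, 120 and 50 in CHG, and 7 and 47 in CHH, and a minimum of 1 gave 399 and 728 in CHH. Windows of 500 bp gave 267 higher and 32 lower in CG, 60 lower in CHG, and 49 higher and 159 lower in CHH. The raised minimum gave 367 higher and 64 lower in CG, 37 lower in CHG, and 46 higher and 118 lower in CHH. Without sites over 50 calls 354 were higher in CG, and 20 higher and 92 lower in CHG, and thinning left 81 lower in CHG. Scanning 1 kb beside genes gave 1 gene of DNA methylation and 0 vegetative genes lower in CG, and 1 maternally expressed gene higher in CHH, between vegetative nuclei and sperm cells.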

Other observations

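The genes of this part were chosen after their values were seen. DME, a glycosylase active in the vegetative cell, had 0 of 28 CG calls methylated in vegetative nuclei, which allows up to 10.7%, against 39.0% in sperm cells and 32.4% in microspores, a change just under the 40 points required (adjusted p = 0.00598, Fisher's exact test). NRPD1, the large subunit of RNA polymerase IV, had 42.7%, 76.3% and 70.3%. HTR10, a histone H3 gene of sperm, had a window with 94.7% CHH methylation in vegetative nuclei, 73.8% in sperm cells and 66.96% in microspores, which did not pass at a minimum of 1 or 8 calls per site. AGL66 had CHH levels of 69.5%, 28.9% and 64.9%, but the call between sperm cells and microspores did not pass at a minimum of 1 or 8 calls per site, and CHH calls of that comparison lay little above the strand background.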
